A study of Homo sapiens with 6 samples.

How the data were processed

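SNU449 cells, a line from a human hepatocellular carcinoma, were grown with a control siRNA (siControl, 3 libraries) or an siRNA against MAD2L1 (siMAD2L1, 3 libraries) and were collected at day 3, per the labels. Total RNA was extracted with Trizol and made into libraries with an NEBNext Ultra RNA kit, per the labels' protocols. The notes on processing by the submitters name fastp, HISAT2, DESeq2 1.16.1 and the genome build hg38, per the submitters' processing notes. The read counter, the annotation and the step from reads to expression values are not given in the sources used here, nor is the strand setting. The deposited table holds TPM (transcript abundance scaled to a fixed library total), 1 column per library, for 60589 genes. Each column had the same sum, as TPM has by construction, so the number of reads behind a value is unknown and no counting interval is given.

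Libraries were grouped by their titles. The columns named for a negative control were taken as siControl and those named for MAD as siMAD2L1, in the order of their numbers. The treatment field names MAD2L1 for siMAD2L1 replicate 1, but MAD2L2 and MAD2L3 for replicates 2 and 3, while all 3 titles name MAD2L1. MAD2L1 and MAD2L2 were therefore read in each library. The labels do not say whether the numbers mark separate cultures, repeat transfections or different siRNAs, so the p-values measure the spread between these libraries.

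The table lists 60232 genes with an Ensembl identifier, 5405 of them joined to an identifier from transcript assembly. A further 357 carry the assembly identifier alone and hold 0.561% of the TPM. Symbols were taken from the table, and gene positions, types, spliced lengths and 3′ UTRs from GENCODE 29 (GRCh38), which held 57974 of the Ensembl identifiers. Values were transformed to log2(TPM + 1). Genes with a mean TPM of at least 1 over the 6 libraries were kept, which left 14790. limma 3.58.1 in R 4.3.3 was fitted with an intensity trend (limma-trend) to siMAD2L1 against siControl without covariates. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of single genes below are from this fit. Log2 fold changes are differences of group means of log2(TPM + 1) and understate the change of genes with low TPM. Folds of genes listed at 0 throughout a group are not given.

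Before the data were examined, 31 gene lists were fixed, together with the tests, the filter and the alternatives except the 1 for transcript length. Of these lists, 29 had at least 5 tested members. Of the leukocyte markers 3 were tested and of the endothelial markers 0, because the rest lay under the filter. Each list was tested with camera at a preset correlation between genes of 0.01, which compares its members with the other genes, and again with an estimated correlation. fry was run beside it. The directional p of fry asks whether the genes of a list move, on balance, in a shared direction, its mixed p asks whether they change in either direction, and neither compares the list with other genes. Values of single libraries were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3.

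The named genes followed a rule fixed with the lists. They are MAD2L1 and MAD2L2; MAD1L1, MAD2L1BP, TRIP13, CDC20, BUB1B and MYC; the 12 largest rises and the 12 largest falls among called genes with a symbol and no overlap between groups, passing over clone-style names; and for each list up to 4 called members with the largest change, or the 2 with the highest TPM where none was called. Not every gene that the rule takes is described. Genes outside the rule are said to be so where they appear.

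The fit and the list test were checked on 10 simulated datasets of 14790 genes for this comparison, with 200 genes changed, 50 at each size. At a log2 change of 0.5 20.8% were recovered, at 1 70%, at 1.5 88.2% and at 2 96.2%. False calls made up 5.86% of the calls. A list shifted by -0.5 was called in all 10 simulations. The noise was drawn for each gene independently, so the list test was not checked on lists whose genes vary together. The changed genes were drawn only from the more highly expressed ones, so recovery at low TPM was not measured.

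The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean TPM of 5, upper-quartile scaling, quantile normalization, TPM rescaled without mitochondrially encoded genes and the 20 highest genes, TPM rescaled over protein-coding genes, limma without a trend, with robust variance or with library weights, a block for the replicate number, an adjusted p of 0.01, each library left out in turn, and siMAD2L1 replicate 1 alone against the controls. Removal of a transcript-length trend from each library was added after the data were seen, and it also takes out each library's overall offset. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the 3′ UTR search and the plots, and R for the permutation tests.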

Results

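RNA was sequenced from SNU449 cells at day 3 after treatment with a control siRNA (siControl, n = 3) or with an siRNA against MAD2L1 (siMAD2L1, n = 3). The values are TPM, and the depth of each library is unknown. Genes with a TPM above 0 numbered 24128 ± 113 (SD, n = 3) in siControl and 23023 ± 564 (SD, n = 3) in siMAD2L1. Across tested genes, Pearson correlations lay between 0.977 and 0.980 within siControl, between 0.969 and 0.980 within siMAD2L1 and between 0.959 and 0.970 across the groups; genes are not independent replicates. The first principal component (37.8% of the variance) separated the groups. On the second (23.4%), siMAD2L1 replicate 1 scored 40.0, against -24.7 and -11.9 for replicates 2 and 3.

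The comparison asks which transcripts differ when MAD2L1, a spindle assembly checkpoint protein that binds CDC20 and holds back anaphase, is knocked down in hepatocellular carcinoma cells. MAD2L1 mRNA in siMAD2L1 stood at 18.2% of the siControl mean. Of the fixed gene lists, 17 of 35 G2/M and mitotic genes and 20 of 37 DNA replication and G1/S genes fell, among them KIF20A, MCM3 and PCNA, as did CDC20. Of 22 NF-kB and inflammatory genes 10 rose and 2 fell, and 11 of 22 immediate early and MAPK output genes rose, among them CCL20, IL1B, IL6 and DUSP5. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose, and all 13 mRNAs encoded in the mitochondrial genome fell. These 5 lists passed camera at a preset correlation, with adjusted p of 0.227 to 0.284 with an estimated correlation.

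MAD2L1 (ENSG00000164109) lies on the minus strand of chromosome 4 from 120055608 to 120067074 (GRCh38). It measured 14.5, 13.7 and 13.9 TPM in the siControl libraries and 4.47, 0.795 and 2.40 TPM in siMAD2L1 replicates 1, 2 and 3. The means were 14.03 ± 0.374 (SD, n = 3) and 2.55 ± 1.84 TPM (SD, n = 3), and the 2 groups did not overlap (exact permutation p = 0.1, the smallest this design allows). The log2 fold change was -2.22 (SE 0.357, limma adjusted p = 0.0105). The adjusted p rose to 0.0597, 0.0547 and 0.0572 without siControl replicate 1, 2 or 3, at log2 fold changes of -2.20, -2.24 and -2.23. MAD2L2, which the treatment field of siMAD2L1 replicate 2 names, measured 145 ± 6.16 TPM in siControl and 138 ± 15.3 TPM in siMAD2L1 (SD, n = 3 each; log2 fold change -0.07, adjusted p = 0.698, exact permutation p = 0.6). In replicate 2 itself MAD2L2 measured 154 TPM, above each siControl library.

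**Figure D1:**
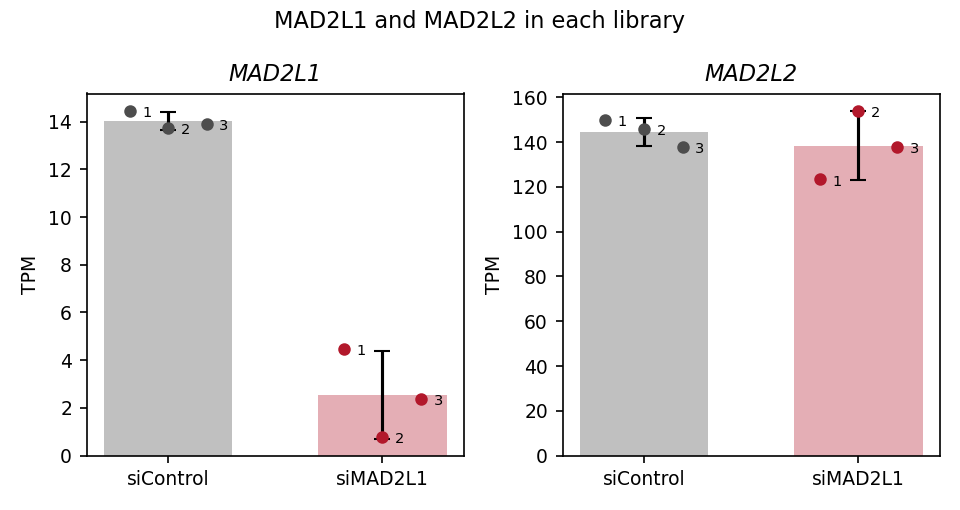
TPM of MAD2L1 and MAD2L2 in the siControl and siMAD2L1 libraries; bars are means, error bars SD (n = 3) and points single libraries. MAD2L1 averaged 14.03 TPM in siControl and 2.55 TPM in siMAD2L1, while the MAD2L2 values of the groups overlapped.

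Of 14790 genes tested, 1446 passed an adjusted p of 0.05 in limma, 525 higher and 921 lower in siMAD2L1 (63.7% lower). With quantile normalization 687 were higher and 701 lower (50.5% lower), with upper-quartile scaling 470 and 1114 (70.3%), with TPM rescaled without mitochondrial and the 20 highest genes 445 and 1216 (73.2%), with TPM rescaled over protein-coding genes 526 and 1028 (66.2%), and with a transcript-length trend removed, an alternative chosen after the data were seen, 834 were higher and 654 lower (44.0% lower). A change of at least 2-fold was found for 264 of the called genes, 111 higher and 153 lower, and 13 called genes were listed at 0 throughout a group. The 2-fold count ranged from 155 (without siControl replicate 3) to 340 (without siMAD2L1 replicate 1) with a library left out, and was 501 with library weights. The groups did not overlap at 4851 genes (32.8%, against 10% by chance). The number of calls fell to 326, 514 and 383 without siControl replicate 1, 2 or 3 and was 2422, 793 and 645 without siMAD2L1 replicate 1, 2 or 3.

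Among the largest rises, KRTAP2-3, a keratin-associated protein, rose from 2.94 to 21.3 TPM. Several genes for secreted proteins were also among them, though secreted proteins were not tested as a set. PI3, the elastase inhibitor elafin, rose from 11.7 to 60.0 TPM (log2 fold change 2.25), INHBA, the activin A subunit, from 15.98 to 76.2 TPM (2.18), and CCL20, a chemokine, from 28.1 to 132 TPM (2.15). WFDC3 (1.92) and CSF3, the granulocyte colony-stimulating factor (1.74), also rose. The 12 largest rises had SE between 0.109 and 0.543 and adjusted p between 0.000688 and 0.0439. SNORA65 was listed at 0 in all siControl libraries and at 4.35, 8.71 and 6.76 TPM in siMAD2L1. TMEM265 was likewise listed at 0 in siControl and at 5.45, 7.53 and 5.85 TPM in siMAD2L1, and RN7SL608P at 0 in siControl and at 2.41, 10.6 and 2.52 TPM in siMAD2L1. C19orf33 (2.16) and the pseudogenes DHFRP1 (2.36) and IKBKGP1 (2.19) lost their calls in fits with a library left out, with adjusted p up to 0.0931, 0.0834 and 0.152. RN7SL608P lost its call likewise, with adjusted p up to 0.0796 without siControl replicate 3.

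The largest falls included ID3, an inhibitor of basic helix-loop-helix transcription factors, from 121 to 24.7 TPM (log2 fold change -2.25), and ADA, adenosine deaminase, from 46.8 to 11.6 TPM (-1.93). The kinase genes ALPK2 (-1.76), PKDCC (-1.73) and SGK2 (-1.65) fell, as did ARV1 (-1.63). SNORA11F and the pseudogene BANF1P1 were listed at 0 in all siMAD2L1 libraries; in siControl SNORA11F measured 2.17, 2.31 and 2.19 TPM and BANF1P1 2.33, 3.63 and 1.27 TPM. The readthrough gene RBM14-RBM4 (-2.32) and the small RNA pseudogene RN7SL656P (-1.65) were also among the 12 largest falls, as was MAD2L1. These 12 had SE between 0.111 and 0.415 and adjusted p between 0.000301 and 0.0448. RBM14-RBM4 lost its call without siControl replicate 3 (adjusted p = 0.0672), BANF1P1 and RN7SL656P without siControl replicate 1 (0.0690 and 0.147). Readthrough genes, pseudogenes and small RNAs share sequence with other genes, so their values are uncertain.

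**Figure D2:**
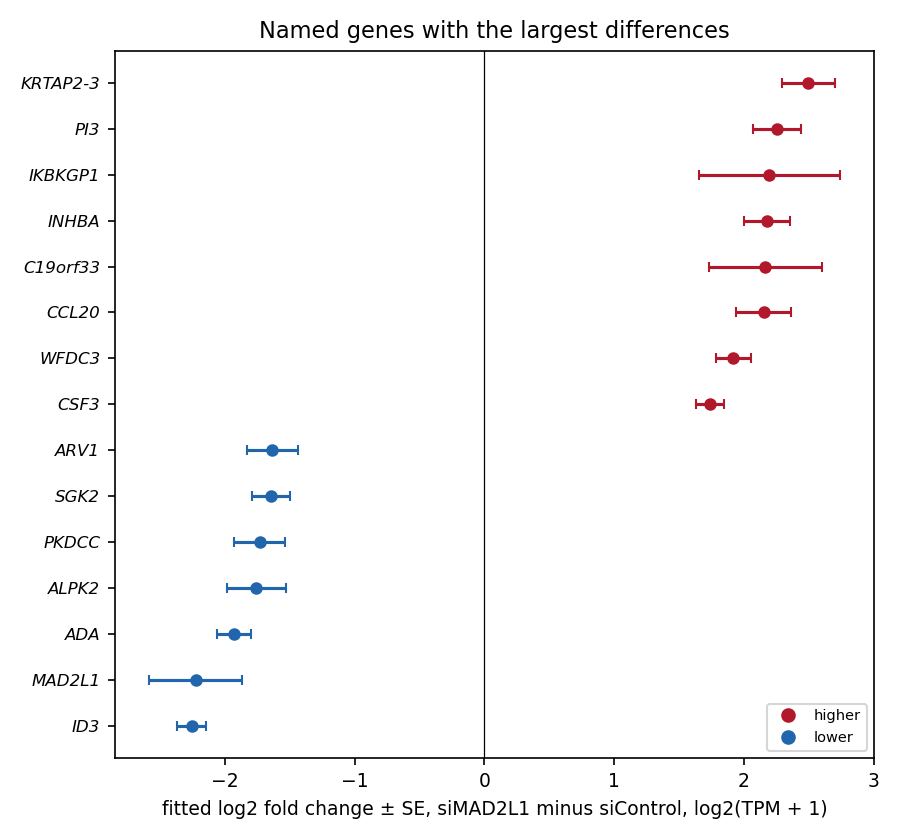
Log2 fold changes of log2(TPM + 1), siMAD2L1 minus siControl, of the named genes with the largest rises and falls, with SE (n = 3 per group); genes listed at 0 in any library are left out. Among the plotted genes PI3 rose (2.25) and ID3 fell (-2.25).

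Among 28 spindle checkpoint and kinetochore genes, 7 fell and the other 21 did not pass (10 fell adjusted over the list alone). CDC20, the activator of the anaphase promoting complex, fell from 84.4 ± 4.08 to 40.0 ± 6.70 TPM (SD, n = 3; log2 fold change -1.07). MAD2L1BP, which binds MAD2L1 and helps to silence the checkpoint, fell (-0.79), as did BIRC5 (-0.77). SPC25 (-0.79) and TRIP13, the ATPase that remodels MAD2L1 (-0.51), passed but lost their calls without siControl replicate 1 (adjusted p = 0.0676 and 0.117). MAD1L1 (-0.38, adjusted p = 0.190) and BUB1B (-0.43, adjusted p = 0.137) did not pass, though BUB1B did without siMAD2L1 replicate 1 (adjusted p = 0.0168). The list lay lower than other genes by camera (median -0.47, adjusted p = 3.66e-06; adjusted p = 0.297 with an estimated correlation).

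Of 35 G2/M and mitotic genes, 17 fell (22 adjusted over the list alone), among them KIF20A (-1.24, from 19.1 to 7.47 TPM), CDCA3 (-0.91), NEK2 (-0.996) and CDC25C (-0.86). NEK2 and CDC25C lost their calls in fits with a library left out, with adjusted p up to 0.0604 without siControl replicate 1 and up to 0.114 without siControl replicate 3. The list median was -0.56 (camera adjusted p = 4.31e-11; adjusted p = 0.284 with an estimated correlation). Of 37 DNA replication and G1/S genes, 20 fell (27 adjusted over the list alone), with the helicase subunits MCM3 (-1.23) and MCM6 (-1.17), the sliding clamp PCNA (-1.14, from 125 to 56.1 TPM) and cyclin E1, CCNE1 (-1.02). Their median was -0.57 (camera adjusted p = 3.57e-12; adjusted p = 0.284 with an estimated correlation). Of 28 cohesin, condensin and anaphase promoting complex genes, 2 fell, NCAPD2 (-0.84) and NCAPD3 (-0.54; adjusted p = 0.158 without siControl replicate 1), and the list did not pass (median -0.17, camera adjusted p = 0.165), though it did without siMAD2L1 replicate 1 (median -0.31, adjusted p = 0.0226), and its median was -0.05 without siMAD2L1 replicate 2. Of 25 DNA damage repair genes 1 fell, EXO1 (-0.73; adjusted p = 0.0982 without siControl replicate 1), at a list median of -0.32 (camera adjusted p = 0.0128; adjusted p = 0.497 with an estimated correlation), -0.21 with quantile normalization and -0.05 in siMAD2L1 replicate 1 alone. The replication-dependent histones did not pass (13 tested, median 0.24, camera adjusted p = 0.0970), though they did without siMAD2L1 replicate 3 (median 0.33, adjusted p = 0.0406), and their median was 0.06 without siMAD2L1 replicate 1 and 0.15 and 0.13 without siControl replicate 1 or 2. Their highest members, H2BC12 (0.34, adjusted p = 0.0663, and 0.00588 with a transcript-length trend removed) and H2BC5 (0.37, adjusted p = 0.358), did not either.

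Of 25 p53 target genes, 4 rose (5 adjusted over the list alone). They were CDKN1A (1.31, from 121 to 304 TPM), the stress-induced SESN2 (1.15), GDF15 (0.73; adjusted p = 0.0609 without siControl replicate 1) and TP53I3 (0.44; adjusted p = 0.182 without siControl replicate 1). The list median was 0.12 (camera adjusted p = 0.0128; adjusted p = 0.284 with an estimated correlation), and by library it was 0.22, -0.10 and 0.15 in siMAD2L1 replicates 1, 2 and 3. It was 0.02 without siControl replicate 2, 0.03 without siMAD2L1 replicate 1 and 0.04 without siMAD2L1 replicate 3, at adjusted p of 0.0281, 0.0105 and 0.0423, and between 0.08 without mitochondrial and the 20 highest genes and 0.23 with quantile normalization over the scalings. Of 26 apoptosis regulators 3 rose and 2 fell (4 and 2 adjusted over the list alone). MCL1, which blocks apoptosis, rose (1.22, from 82.6 to 195 TPM), as did the pro-apoptotic BAK1 (0.51), while the pro-apoptotic PMAIP1 (-0.97) and the caspase-8 inhibitor CFLAR (-0.52) fell. Without siControl replicate 3 the adjusted p of BAK1 was 0.0915 and that of PMAIP1 0.128, and without siControl replicate 1 that of CFLAR was 0.0660. This list did not pass (median 0.04, camera adjusted p = 0.0701), though it did with upper-quartile scaling (0.0423) and with a transcript-length trend removed (0.0411). Its median was 0.21 without siMAD2L1 replicate 2, and by library 0.37, 0.00367 and 0.02.

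Of 22 NF-kB and inflammatory genes, 10 rose and 2 fell (13 and 2 adjusted over the list alone). After CCL20, the largest rises were IL1B (1.61, from 25.8 to 82.9 TPM), CXCL8 (1.31, from 219 to 556 TPM) and IL6 (1.29, from 96.0 to 237 TPM). The 2 that fell, named here after their values were seen, were the chemokine gene CCL2 (-1.01) and TNFAIP2 (-0.53). The list median was 0.46 (camera adjusted p = 4.21e-10; adjusted p = 0.284 with an estimated correlation). Of 22 immediate early and MAPK output genes, 11 rose (14 adjusted over the list alone), with the ERK phosphatases DUSP5 (1.61, from 37.2 to 115 TPM) and DUSP6 (1.42) and the transcription factors KLF6 (1.10) and ATF3 (1.01). Their median was 0.62 (camera adjusted p = 1.4e-13; adjusted p = 0.227 with an estimated correlation).

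The interferon response did not pass as a list by camera (19 tested, median -0.17, adjusted p = 0.305). The directional p of fry for it was 0.0247 after adjustment. Over all genes 2 fell, among them IRF1 (-0.69), and ISG20 rose (0.52), with 1 higher and 4 lower adjusted over the list alone. Of 8 cGAS-STING and nucleic acid sensing genes 2 fell, ADAR (-0.49) and MAVS (-0.47; list median -0.16, camera adjusted p = 0.415). IRF1, ISG20, ADAR and MAVS lost their calls in fits with a library left out, with adjusted p up to 0.0907 for IRF1, 0.136 for ADAR and 0.115 for MAVS without siControl replicate 1 and up to 0.0791 for ISG20 without siControl replicate 3. Of 13 genes of the RNA interference machinery 1 rose, AGO2 (0.57; list median 0.06, camera adjusted p = 0.164). AGO2 lost its call in all 6 fits with a library left out (adjusted p up to 0.129) and in 10 of 20 alternatives in total. That median was 0.17 without siControl replicate 1 or siMAD2L1 replicate 2.

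Of 25 hypoxia and glycolysis genes, 7 rose (10 adjusted over the list alone), with LOX (1.15), NDRG1 (1.12, from 538 to 1161 TPM), BNIP3L (0.81) and the glucose transporter SLC2A1 (0.79). Without siControl replicate 1 the adjusted p of BNIP3L and SLC2A1 rose to 0.128 and 0.0531. The list median was 0.27 (camera adjusted p = 3.86e-08; adjusted p = 0.284 with an estimated correlation), and 0.17 without siMAD2L1 replicate 1. Of 28 cholesterol and fatty acid synthesis genes, 9 fell (12 lower and 1 higher adjusted over the list alone), among them FADS2 (-1.03), fatty acid synthase FASN (-0.82) and ACACA (-0.89), the last with an adjusted p of 0.0558 without siControl replicate 1. Their median was -0.22 (camera adjusted p = 0.00530; adjusted p = 0.323 with an estimated correlation). Of 26 NRF2 and ferroptosis genes 5 rose and 5 fell (7 and 6 adjusted over the list alone), with rises of heme oxygenase HMOX1 (1.32, from 425 to 1059 TPM) and the ferritin heavy chain FTH1 (0.66, from 16682 to 26387 TPM) and a fall of ABCC2 (-0.76). ABCC2 lost its call without siControl replicate 2 (adjusted p = 0.137). FTH1 did not pass when no filter was applied (adjusted p = 0.0710), and the list did not pass (median 0.07, camera adjusted p = 0.0576). It passed with library weights (0.0402), without siControl replicate 3 (0.0499), without siMAD2L1 replicate 2 (0.0423) and with a transcript-length trend removed (0.0272), and its median was -0.04 without siMAD2L1 replicate 1.

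The integrated stress and unfolded protein response genes did not pass as a list (27 tested, 4 higher and 4 lower, 5 and 8 adjusted over the list alone, median 0.03, camera adjusted p = 0.689). After SESN2, its largest changes were DNAJB9 (1.02), PHGDH (-0.52) and ASNS (-0.45), with adjusted p up to 0.0672 without siControl replicate 3 for DNAJB9 and up to 0.0672 and 0.0906 without siControl replicate 1 for PHGDH and ASNS. Of 32 MYC and target genes, 5 fell and 2 rose (9 and 2 adjusted over the list alone). DKC1, which encodes dyskerin (-1.40, from 56.2 to 20.7 TPM), NME1 (-1.01) and IMPDH2 (-0.49; adjusted p = 0.0775 without siControl replicate 3) fell, ODC1 rose (0.75), and MYC itself did not pass (0.08, adjusted p = 0.711). The 3′ UTRs of DKC1 and NME1 hold the 8-mer CCATCTGA, which also occurs in the MAD2L1 coding sequence. The list median was -0.24 (camera adjusted p = 0.0128; adjusted p = 0.399 with an estimated correlation), and its call ended without siControl replicate 3 (adjusted p = 0.0563) and with library weights (adjusted p = 0.0939). Of 30 autophagy and lysosome genes 3 rose, ULK1 (0.71), the protease cathepsin L, CTSL (0.65), and WIPI1 (0.47), with 6 higher and 1 lower adjusted over the list alone. ULK1 lost its call without siControl replicate 1 (adjusted p = 0.0660) and WIPI1 without siControl replicate 3 (0.140). Their median was 0.13 (camera adjusted p = 0.000714; adjusted p = 0.322 with an estimated correlation) and 0.07 without siMAD2L1 replicate 1 and 0.21 with a transcript-length trend removed, and the call ended with quantile normalization (adjusted p = 0.0572).

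Mitochondrial transcripts took a smaller share of the TPM in siMAD2L1, with 9.84% ± 0.896 against 15.3% ± 0.0603 in siControl (SD, n = 3 each; exact permutation p = 0.1). All 13 mitochondrially encoded mRNAs fell, both over all genes and adjusted over the list alone, among them MT-ATP8 (-1.02), MT-ATP6 (-0.93), MT-CO3 (-0.89) and MT-ND3 (-0.74). MT-ATP8 and MT-ATP6 overlap, so their values are uncertain. MT-ATP8 lost its call with a transcript-length trend removed (adjusted p = 0.0741), and MT-ND3 lost its call without siControl replicate 3 (adjusted p = 0.154). The median was -0.62 (camera adjusted p = 1.7e-11; adjusted p = 0.284 with an estimated correlation), and by library -0.78, -0.70 and -0.43. Of 31 nuclear oxidative phosphorylation genes 3 fell, NDUFB10 (-0.43), NDUFB3 (-0.37) and ATP5F1A (-0.25), and the list did not pass (median -0.02, camera adjusted p = 0.733). These 3 lost their calls without siControl replicate 1 (adjusted p = 0.123, 0.155 and 0.187). None of the 39 cytosolic ribosomal protein genes passed in limma over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05. Their median of 0.11 lay above other genes (camera adjusted p = 3.66e-06; adjusted p = 0.449 with an estimated correlation), with RPL10 at 0.27 (adjusted p = 0.0613, and 0.0209 without siMAD2L1 replicate 1) and RPL13 at 0.12 (adjusted p = 0.522), but was -0.01 with quantile normalization (adjusted p = 0.774) 0.05 without siMAD2L1 replicate 2 (adjusted p = 0.0120) and 0.20 with a transcript-length trend removed.

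Of 11 hepatocyte identity genes, 4 fell over all genes and adjusted over the list alone. They were the fibrinogen chains FGA (-1.50), FGG (-1.48) and FGB (-1.17) and transferrin, TF (-0.97). Control levels were low, at 4.44, 15.7, 7.42 and 8.83 TPM, and the adjusted p rose to 0.0698 for FGG without siControl replicate 2 and to 0.0778 and 0.0870 for FGB and TF without siControl replicate 1. The list median was -0.40 (camera adjusted p = 0.0147; adjusted p = 0.446 with an estimated correlation), and -0.24 with quantile normalization. Over 24 members with no filter the median was only -0.07 and the call ended (adjusted p = 0.2497). Of 13 epithelial genes 3 fell, the keratins KRT7 (-0.61), KRT18 (-0.55) and KRT8 (-0.44; list median -0.21, camera adjusted p = 0.0820). KRT7 lost its call without siControl replicate 3 (adjusted p = 0.106) and KRT8 without siControl replicate 1 (0.0638). Of 11 liver stem and oncofetal genes 1 fell, CD24 (-0.87; adjusted p = 0.0761 without siControl replicate 2; list median -0.04, camera adjusted p = 0.946).

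Of 29 TGF-beta, matrix and mesenchymal genes, 3 rose and 4 fell (4 and 5 adjusted over the list alone), with a rise of TIMP1 (0.89) and falls of the collagen gene COL1A2 (-0.74) and of TWIST1 (-0.59; adjusted p = 0.0878 without siControl replicate 3). The list did not pass (median 0.01, camera adjusted p = 0.391). Of 19 YAP/TEAD target genes 2 rose and 4 fell (4 and 4 adjusted over the list alone). Tissue factor, F3 (1.51, from 51.1 to 149 TPM), and IGFBP3 (0.97) rose, and AJUBA (-1.20) and NUAK2 (-0.88) fell, at a list median of -0.20 (camera adjusted p = 0.689). Markers of other liver cell types did not pass as lists. The stellate cell markers had a median of -0.23 (7 tested, camera adjusted p = 0.422), with 1 lower adjusted over the list alone, COL1A1 at -0.44 (adjusted p = 0.0566, from 0.00401 to 0.279 over 20 alternatives, 6 of which it passed, among them the fit without siMAD2L1 replicate 1 at 0.0381) and RGS5 at 0.36 (adjusted p = 0.444). The biliary markers had a median of -0.14 (8 tested, camera adjusted p = 0.308), with a fall of KRT7.

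**Figure D3:**
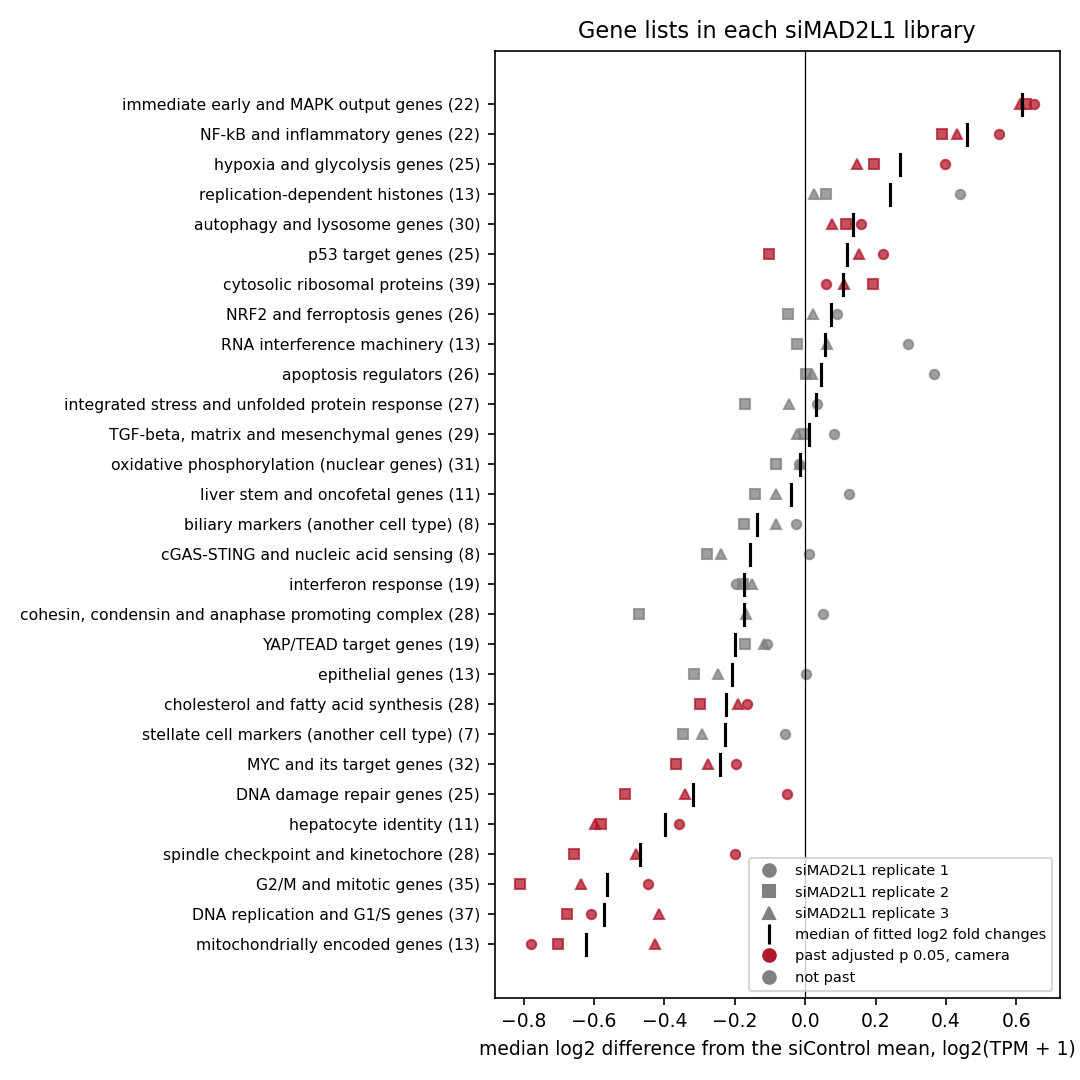
Log2 fold changes, siMAD2L1 minus siControl, of the gene lists, on the scale of log2(TPM + 1); points are list medians in each siMAD2L1 library against the siControl mean, ticks are medians of the fitted changes, and red marks lists past an adjusted p of 0.05 by camera. The ticks range from -0.62 for mitochondrially encoded genes to 0.62 for immediate early and MAPK output genes.

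In total 14 of the 29 lists passed camera at the preset correlation, 6 higher and 8 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.227 and 4 lists had an unadjusted p under 0.05; fry called 11 lists by its directional p and 26 by its mixed p. The list calls by camera therefore rest on the preset correlation of 0.01. Of these 14 lists, 10 also passed the directional p of fry, which does not compare a list with other genes. The p53, DNA repair, autophagy and ribosomal lists did not (fry adjusted p = 0.0617, 0.0730, 0.0705 and 0.216). Besides MAD2L1, whose call ended in 3 of the 6 fits with a library left out, 105 named genes passed, with adjusted p between 0.000301 and 0.0498, and 58 of them kept their calls in all 6 fits. Where a call is said to end without a library, the fit with the highest adjusted p is given, and most such calls ended in several fits. Besides AGO2, they ended in 5 of the 6 for TRIP13, IKBKGP1, RN7SL656P, NCAPD3, TP53I3, PMAIP1, BAK1, ISG20, ADAR, MAVS, ASNS, ABCC2, TWIST1, CD24, NDUFB3, ATP5F1A and MT-ND3, and in 4 for DHFRP1, CDC25C, EXO1, IRF1, DNAJB9, BNIP3L, KRT7, FGG, WIPI1 and NDUFB10. They ended in 3 for RN7SL608P, C19orf33, BANF1P1, IMPDH2, FGB, TF and ULK1, in 2 for SPC25, GDF15, CFLAR and PHGDH, and in 1 for RBM14-RBM4, NEK2, ACACA, SLC2A1 and KRT8. Of 10 named genes that did not pass, BUB1B, MYC, RPL10, H2BC12 and COL1A1 passed with library weights (adjusted p = 0.00451, 0.0366, 0.00521, 0.0422 and 0.00401). Of the 15 lists that did not pass, 11 had a median that moved by over 1.5 times when a library was left out, and 5 a median that changed sign. The counts adjusted over the list alone were those over all genes for the cohesin, DNA repair, histone, nucleic acid sensing, RNA interference, oxidative phosphorylation, epithelial, oncofetal and biliary lists. In siMAD2L1 replicate 1 alone against the controls 9 lists passed, and the calls of the p53, DNA repair, cholesterol, hepatocyte and ribosomal lists ended.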

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

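The alternatives were fixed beforehand except the removal of a transcript-length trend, which was chosen after the data were seen. The 1446 calls became 727 with no filter (more genes tested), 952 without the trend in limma, 4860 with library weights, and 359 at an adjusted p of 0.01. They ranged from 326 to 2422 with a library left out, which leaves fewer samples. There were 326, 514 and 383 without siControl replicate 1, 2 or 3 and 2422, 793 and 645 without siMAD2L1 replicate 1, 2 or 3. Fewer samples do not account for the rise without siMAD2L1 replicate 1. With the replicate number as a block there were 868 calls. The fit without pairs was fixed beforehand, since the labels do not say that the numbers mark a batch or day. Same-numbered libraries deviated together at r of only 0.0190, 0.00898 and 0.0631 across genes. Replicates 1 and 3 matched their own number best and replicate 2 did not, so these r values do not settle whether the libraries were paired. The other alternatives gave 1228 to 1661 calls. For the changes without the trend, with library weights, with the block and without siMAD2L1 replicate 1 the cause was not tested. MAD2L1 kept its fall, from -2.61 to -1.80 with a library left out (adjusted p 0.00305 to 0.0597, above 0.05 without siControl replicate 1, 2 or 3 at 0.0597, 0.0547 and 0.0572) and from -2.70 to -2.13 under 13 other settings, and was -1.46 in siMAD2L1 replicate 1 alone, where the lone library is assumed to vary like the controls. Of 29 lists, 14 passed camera, 0 with an estimated correlation (4 at an unadjusted p under 0.05), 9 in siMAD2L1 replicate 1 alone against the controls, and 14 to 15 with a library left out, of which 13 to 14 were among the main 14; fry called 11, 10 of them among the 14; the MYC list lost its call without siControl replicate 3 (adjusted p = 0.0563). The mitochondrially encoded list could not be tested on TPM rescaled without those genes. No scaling moved the median of all genes by over 0.1. Count-based tools (edgeR, DESeq2) were not run, since the file holds TPM. Of 105 named genes past the threshold besides MAD2L1, 55 stayed past it under each alternative run, and of 2077 pairs of gene and alternative 1784 kept the call and 293 lost it; of 199 pairs for the 10 named genes not past, 14 gained it. Read depth is unknown, so what it limits could not be measured.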

Other observations

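The gene groups in the next paragraph, the 3 tests of the motif pattern, the test of seed matches as the cause of the excess of falls, and the test of a length trend as the whole of the difference of siMAD2L1 replicate 1 were chosen only after the result was seen.

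In groups that were not among the fixed lists, called genes had adjusted p between 0.000301 and 0.0351. Of 13 genes of BMP signalling, 4 were lower and 2 higher. Besides ID3 (-2.25), the inhibitory SMAD6 (-1.27) and BAMBI (-1.10, from 80.8 to 37.8 TPM) fell and GREM1, a secreted BMP antagonist, rose (1.19, from 20.03 to 47.4 TPM), while ID1 (-0.42) and the antagonist NOG (0.59) lost their calls in 1 and 4 of 6 fits with a library left out (adjusted p up to 0.0574 and 0.0652). Of 4 metallothionein genes 2 rose, MT1X (1.08, from 212 to 451 TPM) and MT2A (0.90, from 4418 to 8284 TPM); these genes are close copies of each other, so their values are uncertain. Of 15 integrin genes 3 rose, ITGB3 (1.29, from 102 to 252 TPM), ITGA5 (1.10) and ITGA2 (1.29; call lost in 4 of 6 fits with a library left out, adjusted p up to 0.1002). Of 11 matrix metalloproteinase genes 2 rose and 1 fell, with MMP1 from 105 to 305 TPM (1.51), MMP3 at 1.23 (call lost in 3 of 6 fits, adjusted p up to 0.0744) and MMP24 at -0.50 (in 5 of 6, up to 0.126). Of 10 coagulation and plasminogen genes 4 rose, among them F3 (1.51), the inhibitor TFPI2 (1.19) and the urokinase receptor PLAUR (0.73), while urokinase itself, PLAU, fell (-0.72).

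Genes with the 7-mer CCATCTG in the 3′ UTR lay lower in siMAD2L1 by an adjusted log2 difference of -0.0553 (1911 of 11874 genes). Its z of -5.87 was the lowest of 16216 7-mers in a regression that allows for UTR length, AU content and expression. CCATCTG occurs once in the MAD2L1 mRNA, at positions 115 to 121 of the coding sequence, in exon 2 of 5 (chromosome 4, 120065771 to 120065777, GRCh38). Of the 7-mers tested 3.69% occur in that coding sequence and 26.1% in the whole mRNA. Which part of the mRNA the siRNA targets is not known. An effect in 1 library alone is argued against, since CCATCTG also ranked lowest in each search without 1 siMAD2L1 library and 1 control, and its z in the pair left out was -5.52, -3.90 and -5.11, against 0.0587, -0.0601 and -0.109 between the controls. The 419 7-mers with the same bases in another order had a median z of -0.24. Thus 7-mers of these bases did not in general lie low after the adjustment. The regression had already removed AU content, so this median cannot decide on base composition as a cause. Genes with the 8-mer CCATCTGA lay lower than the other genes with CCATCTG, by an adjusted log2 difference of -0.053 (SE 0.0192). That 8-mer joins CCATCTG and CATCTGA, which ranked 1 and 2 in the same search. The comparison thus draws on the values that ranked them and is no separate support for a seed effect. A candidate explanation is off-target silencing through the seed of a MAD2L1 siRNA. It stays open because the siRNA sequence is not given in the sources used here, a match in the coding sequence also went with lower values (z -4.31), the siControl siRNA was not set against untreated cells, and a biological cause through a microRNA or RNA-binding protein was not tested.

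Genes called lower with the 8-mer in the 3′ UTR include DKC1 (-1.40), MAP2K6 (-1.57) and NME1 (-1.01), and with the 7-mer NABP2 (-1.52), CLDN2 (-1.57) and CYB5B (-1.14). Before adjustment the median log2 fold change was -0.114 in the 433 genes with the 8-mer, but -0.0654 in the 1478 genes with the 7-mer and no 8-mer, against -0.0645 in the 6830 genes without the 6-mer, so for most genes with the site a lower median appears only after adjustment. The share called lower was 9.70%, 8.86% and 6.69% of these groups. It was 4.10% of the 926 genes with CATCTGA and no CCATCTG, and 6.03% of the 2207 genes with the 6-mer CATCTG alone. The share therefore did not follow the length of the match throughout. The adjusted log2 shifts of these last groups were -0.0443 and -0.00100. Other low 7-mers were CATCTGA (z -5.63), which overlaps CCATCTG, and GTTCAAG (z -5.04), AACCCGG (z -4.70), GAGAATC (z -4.66) and GGCTCAC (z -4.63), which do not occur in the MAD2L1 mRNA and which a seed in it does not account for. At the other end of the ranking stood TTATTTA (z 5.17) and TATTTAT (z 5.02), which hold the core of AU-rich elements.

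siMAD2L1 replicate 1 lay apart from replicates 2 and 3. Some values go with a weaker response in it (MAD2L1 at 31.9% of control against 5.66% and 17.1%; spindle list median -0.20 against -0.66 and -0.48) and others do not (immediate early list 0.65 against 0.63 and 0.61; mitochondrially encoded list -0.78 against -0.70 and -0.43). Across all genes the differences of replicate 1 from replicates 2 and 3 correlated with those of the control mean at r of only 0.0261 and 0.0844. Variation between single libraries also lowers this r (root mean square distance 0.414 between replicates 2 and 3, 0.550 between 1 and 2). Such a low r therefore cannot decide on a partly weaker response or partly admixed control RNA. Both stay open, as does a weaker response of the spindle genes. RNA quality or library preparation that follows transcript length goes with part of the difference. Each library was set against the mean of the others in its group. The Spearman rho of this difference with spliced length was 0.275 for replicate 1 across 14363 genes. It was -0.292 and -0.0663 for siMAD2L1 replicates 2 and 3 and -0.0464, 0.140 and -0.135 for the siControl libraries. Replicate 2 thus departs as much the other way. Once a length trend was removed, 64.5% of the excess distance was left. The length used is that of the longest annotated transcript of a gene, which need not be the one expressed. What was left therefore argues against a trend with this length as the whole, but cannot decide on RNA quality as the whole. A different siRNA or culture for this library may also play a part. The treatment field names MAD2L1 for replicate 1, but MAD2L2 and MAD2L3 for replicates 2 and 3. Whether these names mark different siRNAs is not stated, so this could not be tested.

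More genes were called lower than higher (63.7%). A scale shift of the whole library cannot be told apart from a true excess, since the lower share was 50.5% with quantile normalization, which gives every library the same distribution by construction, but 70.3%, 73.2% and 66.2% with the other scalings. It was 44.0% with the length trend removed, which also takes out each library's overall offset. The median log2 fold change of the tested genes was then 0.00356, against -0.00294 with quantile normalization and -0.0824 as reported. The 44.0% therefore cannot be credited to transcript length alone. The lower share was 52.1% without siControl replicate 2, so the excess depends on the processing and on single libraries. Matches of the 6-mer CATCTG in 3′ UTRs are argued against as its whole cause. Of the 736 called genes without that 6-mer 62.1% were lower, against 63.0% of all called genes with a 3′ UTR. Matches in coding sequences and matches of any other seed were left in, so seed matches in general stay open. A true excess of falls in cells short of MAD2L1 stays open, as TPM cannot show a change of total RNA.

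Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many calls as the real split, the real split itself (1446 genes; highest other 1), and likewise for the lists by camera (14; highest other 11). With 10 splits a share under 0.05 cannot be reached. At the preset correlation the list test called up to 11 lists in splits that mix the groups. Each of those splits keeps most libraries of a group on the same side, and so keeps part of the real difference. Their list calls are therefore not a count of false calls. The real difference also widens the spread within the mixed groups, so few gene calls there were likely beforehand.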
